A study of Mus musculus with 4 samples.

How the data were processed

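RNA of cultured mouse melanocytes was measured on 4 Affymetrix mouse expression arrays, 2 of a non-pigmented and 2 of a pigmented cell line, with 1 labelled RNA sample per array. The deposited values are probe set intensities on a linear scale. Per the submitters' processing notes they were made with Affymetrix Expression Console, and neither its version nor the summary algorithm is given in the sources used here. In each deposited column the mean signal after trimming 2% of the probe sets at either end was 500, so the authors had scaled the intensity values to a common level per array. Scaling of this kind equalises the arrays in bulk only. It does not correct differences in RNA integrity, and the files used here hold no background or detection column, so a dim probe set could not be separated from background.

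Of 45101 probe sets, 64 were controls and were left out of the tests. The platform annotation gave a single gene symbol for 34945 probe sets, several symbols for 932 and none for 9160. Symbols were compared with the RefSeq table through the Entrez number: 34741 probe sets matched and 0 symbols changed. Each of the 18193 genes was represented by the probe set with the highest mean over the 4 arrays. Genes whose mean log2 value was under the 40th percentile of all probe sets (a log2 value of 6.44, or a signal of 70.7) were left out, which removed 5635 genes and left 12558. Tests were made on log2(signal + 16). Differences are on that scale, pigmented minus non-pigmented, and understate the change of dim genes.

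Differences between the groups were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with no other term, and p-values were adjusted by the Benjamini-Hochberg method over the 12558 genes. A gene was called at an adjusted p under 0.05. Errors after ± beside a difference are standard errors from limma, and those beside a group mean are SDs of 2 arrays. The number of arrays limits the precision: with 2 against 2, the smallest two-sided p of an exact permutation test is 0.333. The labels do not say that the arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Gene lists, 23 of pathways and 6 of markers of other cell types, were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment within each kind of list, and again with an estimated correlation and with fry. The lists held 749 genes with the sex chromosome genes, of which 700 were on the array. Camera with an estimated correlation draws on the residual degrees of freedom, 2 between the lines and 1 with a block. Few lists can pass it then, so a miss there does not decide against a list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

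The lists, the tests and the rule for named genes were fixed before the data were examined. The rule took the 12 largest positive and 12 largest negative differences among called genes with an absolute log2 difference of at least 1 and the same direction in both dates, the tyrosinase gene, up to 4 tested members with the smallest p of each list described, the sex chromosome genes, and the 3 genes with the smallest p in each direction of the comparison of dates. Other list members were named where a count, a test or a plot needed them, and were chosen after their values were seen.

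The titles carry 2 dates, and each date is shared by 1 array of either group. Across genes, the deviations of same-date arrays from their group means correlated at -0.51. With 2 arrays per line the deviations of a line mirror each other, so this is the value of the RNA integrity pairs described next (0.51) with its sign turned, and it does not exclude a smaller effect of the date. The fit with the date as a block was an alternative fixed in advance. The Gapdh and Actb control probe sets divided the arrays in another way, into 2 with a lost 5′ signal (a Gapdh 3′ to 5′ ratio over 3) and 2 without, with 1 array of either group in each class. The fit with this RNA integrity pair as a block was added after the data were seen. Other alternatives were quantile normalization, centring on the median, no filter and a filter at the 60th percentile, eBayes without trend and with robust estimation, the mean of a gene's probe sets, probe sets unique to a gene, pseudocounts of 1 and 64, and leaving out each array in turn. In the last, the group left with 1 array was assumed to vary like the other.

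The code was tested on simulated data for the comparison of the groups, with 12558 genes at their real means, 200 of them changed in each of 20 runs. A first simulation gave each gene its moderated spread and returned 237 false calls among 2013, or 11.8%, above the limit of 10% set for the test. A second simulation was added to find the reason, with spreads drawn from limma's fitted prior, and returned 48 false calls among 747, or 6.43%. limma estimated 11.6 prior degrees of freedom in the first and 4.30 in the second, against 4.22 in the real data, so the excess came with spreads that do not follow limma's prior. By this measure the spreads of the first simulation were unlike the real ones, while those of the second were close to them by construction. The share of false calls among the real ones may still lie above the nominal level. Genes changed by a log2 size of 4 were recovered in 99.2% and 52.0% of cases, those of size 2 in 32.6% and 0.896%, and those of size 1 in 1.04% and 0% (first and second simulation). All simulated genes were independent, which real genes are not. A list of 25 genes shifted by a log2 size of 1 was found by camera in 20 of 20 runs of either simulation. An unshifted list was found in 0 of 20 runs of the first and 1 of 20 of the second.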

Results

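Gene expression was compared between 2 mouse melanocyte lines on a Balb/c background. The non-pigmented line is homozygous for a point mutation in the gene of tyrosinase, the enzyme that starts melanin synthesis, and in the pigmented line that mutation was corrected. Total RNA from skin melanocytes grown with a phorbol ester was hybridised to 4 arrays, 2 per line. The median probe set signal was 111 and 99.7 in non-pigmented replicates 1 and 2, and 130 and 126 in pigmented replicates 1 and 2.

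The arrays differed in the 3′ to 5′ ratio of control probe sets, which is taken here as a measure of RNA integrity. The ratio of 3′ to 5′ control signal of Gapdh was 0.903 in non-pigmented replicate 1 and 0.864 in pigmented replicate 1, but 20.2 in non-pigmented replicate 2 and 16.8 in pigmented replicate 2. For Actb the ratios were 1.21 and 1.33 in the former pair and 9.96 and 12.2 in the latter. The 5′ signal of the Cre control was also higher in the latter pair (14001 and 18649, against 5702 and 6463). So was that of the BioC control (1138 and 1662, against 513 and 646). A difference in labelling or RNA input was not tested. Arrays of a line nevertheless resembled each other most. Across genes, which are not independent replicates, the correlation was 0.910 between the non-pigmented and 0.862 between the pigmented arrays, and 0.722 to 0.819 between arrays of different lines.

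Several pigment genes, among them Tyr and Oca2, were higher in the pigmented line. Several genes of the matrix list and of the Schwann cell and neural crest progenitor list, among them Mgp and S100b, were higher in the non-pigmented line. With limma, 422 of 12558 genes (3.36%) differed, of which 167 were higher and 255 lower in the pigmented line, and 1735 genes had an unadjusted p under 0.05. The called differences were large, which the test itself largely fixes: the simulations recovered at most 32.6% of changes of a log2 size of 2. Over all tested genes the SD of the log2 differences was 1.12. The smallest absolute log2 difference among the called genes was 1.90 and the median 3.82, or 14.1-fold. Of the called genes, 70 were higher and 115 lower by at least 16-fold. In 210 of the 422, and in 123 of these 185, the mean of the dimmer line lay below the log2 value of 6.44 used as the filter, so their sizes depend on the pseudocount. All 422 had the same direction in both dates and in both RNA integrity pairs, which their selection by size and spread largely fixes. Of all tested genes 50.8% and 69.4% did. With the integrity pair as a block, 884 genes were called, 341 higher and 543 lower, among them all 422. Without single arrays the count was 294 (non-pigmented replicate 1), 234 (non-pigmented replicate 2), 772 (pigmented replicate 1) or 568 (pigmented replicate 2).

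Tyr (Entrez gene 22173) was itself among the genes that rose most. Its mean log2 value was 13.80 ± 0.40 (SD, n = 2) in the pigmented and 7.11 ± 1.04 (SD, n = 2) in the non-pigmented line, a log2 difference of 6.69 ± 0.60, or 103-fold, with an adjusted p of 0.00618 by limma. All 3 probe sets of Tyr were higher in the pigmented line, by 6.69, 4.01 and 7.21. The difference was 5.67 within the first date and 7.70 within the second. A point mutation need not alter the RNA level, so this checks the labels only in part.

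In 9 of the 12 genes with the largest rises the non-pigmented mean lay below that value, and in 11 of the 12 with the largest falls the pigmented mean did, so their order has no meaning. S1pr3, a receptor for sphingosine 1-phosphate, rose by 9.09 ± 0.50 (7.55 with a pseudocount of 64 and 10.77 with 1), and Cyba, a subunit of the NADPH oxidase, by 8.39 ± 0.43 (6.71 and 10.11). Bex1 rose by 7.80, Cd200r4 by 7.38 and Apoe, which encodes a lipid carrier, by 7.25. Tspan10 rose by 6.72, Bace2, a protease that cleaves the melanosomal protein Pmel, by 6.62, Mrgprb1 by 6.53, Pla2g2e, a secreted phospholipase, by 6.48, Dynlt3, a dynein light chain, by 6.37 and Oca2, a melanosomal membrane protein, by 6.27. Adjusted p-values of these genes lay between 0.00512 (S1pr3) and 0.00702 (Bex1).

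Among the 12 genes that fell most, Serpina3n, a protease inhibitor, fell by 7.70 ± 0.62 and F3, the tissue factor that starts coagulation, fell by 7.44 ± 0.70. Rhox5, a homeobox gene of the reproductive tract, fell by 7.08, Pcolce, an enhancer of procollagen processing, fell by 6.96, 2310057J18Rik fell by 6.87 and Lcn2, an iron-binding lipocalin, fell by 6.85. Col2a1, a cartilage collagen, fell by 6.79, Mgp, an inhibitor of matrix calcification, fell by 6.75, and Tnnt2, a cardiac troponin, fell by 6.74, with 2 of its 3 probe sets in that direction. Atp1b2 fell by 6.74, the growth factor receptor gene Fgfr1 fell by 6.61 and Prss23 fell by 6.51. The highest adjusted p among them was 0.0164, for Col2a1.

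**Figure D1:**
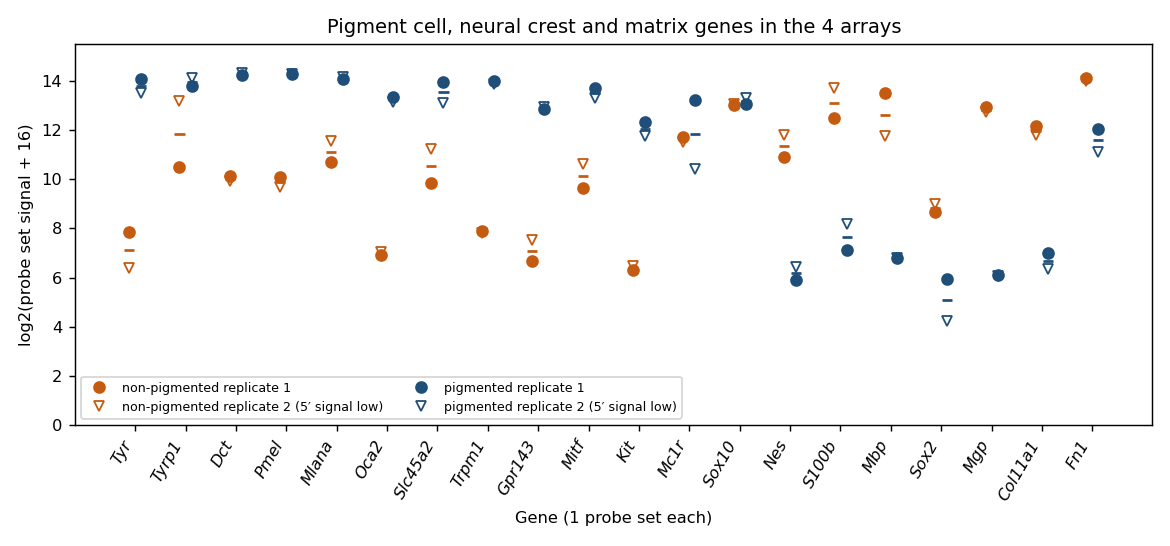
Values of 20 genes in each of the 4 arrays, as log2(probe set signal + 16), with short lines at the group means of 2 arrays and open triangles for the arrays with low 5′ signal. Tyr and Oca2 are higher in both pigmented arrays than in both non-pigmented ones, Mgp and S100b are lower, and Sox10 lies close together (difference 0.16).

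Of the 23 pathway lists, 11 passed camera at the preset correlation, 0 with an estimated correlation, and 3 passed fry, those of melanin synthesis, melanocyte transcription factors and inflammatory genes. Camera with an estimated correlation had 2 residual degrees of freedom, so its 0 decides little. The estimated correlation was also above the preset 0.01 in some of the 11 lists. It was 0.94 for cell cycle, 0.44 for interferon, 0.30 for MAPK, 0.18 for extracellular matrix, 0.10 for antigen presentation and 0.02 for glycolysis. For these lists the camera p at the preset correlation may be too small. In the other lists that passed, the estimated correlation lay below 0.01. Of 19 melanin synthesis and melanosome matrix genes tested, 12 rose and the other 7 did not pass, with Tpcn2 at -0.59 and Mfsd12 at -0.06, and 15 rose when adjusted over the list alone. The mean difference was 3.79 and the median 4.25. The largest evidence was for Trpm1, a cation channel (6.07 ± 0.39), Oca2 (6.27 ± 0.41), Apoe (7.25 ± 0.49) and Gpr143, a melanosomal receptor (5.78 ± 0.47). Dct, an enzyme downstream of tyrosinase, rose by 4.25, the fibril protein gene Pmel by 4.38 and Mlana by 2.99. Tyrp1 had a difference of 2.11 ± 0.83 with an adjusted p of 0.332 and Slc45a2 one of 2.99 ± 0.57 with an adjusted p of 0.0522 (0.0375 with the integrity pair as a block). By camera the adjusted p was 1.23e-18, against an adjusted p = 0.228 with an estimated correlation. That correlation was -0.02, below the preset 0.01, so the higher p came with the fewer degrees of freedom of that test. Medians within the 2 dates were 4.21 and 4.30.

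Of 29 genes of melanosome biogenesis and transport, 3 rose and 26 did not pass, and 8 rose when adjusted over the list alone and 8 with the integrity pair as a block. The 3 were Sytl2 (6.02 ± 0.41) and Rab27a (3.26 ± 0.46), which tether melanosomes and other vesicles, and Lyst (3.21 ± 0.53), a regulator of lysosome-related organelles. Rab38 had a difference of 2.98 with an adjusted p of 0.0737 (0.0254 with the integrity pair as a block). Camera gave an adjusted p of 0.00169, against an adjusted p = 0.376 with an estimated correlation.

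Melanocyte transcription factors and receptors moved in both directions. Of 20 tested, 5 rose and 2 fell, and 7 rose and 3 fell when adjusted over the list alone. With the integrity pair as a block 6 rose and 3 fell. Kit, the stem cell factor receptor, rose by 5.66 ± 0.44 and Met by 3.65 ± 0.37. Mitf, the master regulator of pigment genes, rose by 3.36 ± 0.46 and Ednrb, an endothelin receptor, by 5.69 ± 0.82. The fifth was Cdk2 (3.02), a cyclin-dependent kinase that the list also holds. Tfap2b fell by 4.43 ± 0.67 and Erbb3 fell by 2.28 ± 0.40, the latter in 1 of 2 probe sets and not past the test with the date as a block (adjusted p of 0.112). Sox10, a neural crest factor, differed by 0.16 and the melanocortin receptor gene Mc1r by 0.21 ± 0.87, and neither passed. The list's camera adjusted p was 0.0304. It was 0.0679 with the integrity pair as a block and 0.0767 without pigmented replicate 1, and the adjusted p = 0.383 with an estimated correlation.

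Of 11 Schwann cell and neural crest progenitor markers tested, 5 fell in the pigmented line and 6 did not pass, among them Gfap (-2.42), Cdh19 (-0.59) and Mal (1.76), and 8 fell and 1 rose when adjusted over the list alone. With the integrity pair as a block 6 fell and 0 rose. Mbp, a myelin protein gene, fell by 5.83 ± 0.64, S100b fell by 5.45 ± 0.60, Nes, an intermediate filament gene of progenitors, fell by 5.17 ± 0.50, Sox2 fell by 3.75 ± 0.65 and Pmp22 fell by 2.79 ± 0.48. For Nes, 2 of 3 probe sets had this direction. The mean difference of the list was -2.53, with a camera adjusted p of 3.88e-07, against an adjusted p = 0.201 with an estimated correlation. The fry adjusted p of the list was 0.0694, and fry passed 0 of the 6 marker lists. Medians within the dates were -2.41 and -2.90.

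Markers of the remaining cell types shifted in no list by camera. Of 6 keratinocyte markers tested Krt10 fell, by a log2 difference of -3.02 ± 0.54, and the list had a mean of -0.44 but a median of 0.63. Pkp1 had a difference of -2.51 with an adjusted p of 0.0601 (0.0418 with the integrity pair as a block). None of the 8 fibroblast markers was called by limma, with 1 at an unadjusted p under 0.05 (Col1a2, difference 2.11, adjusted p of 0.0766, and 0.0308 with the integrity pair as a block). The camera adjusted p was 0.946 for the keratinocyte, fibroblast, immune and endothelial lists, and 0.450 for the muscle list. By limma 0 of 8 immune, 0 of 2 endothelial and 0 of 5 muscle genes were called, with 1, 0 and 2 at an unadjusted p under 0.05. With the integrity pair as a block Acta2 (adjusted p of 0.0416) and Actg2 (0.0135) of the muscle list passed. The 2 endothelial genes had a mean of -0.04 while camera gave the direction as up. Xist had a difference of 1.47 with an adjusted p of 0.279, and Kdm5d, Eif2s3y and Uty were too dim to be tested. Ddx3y was not analysed here.

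Of 34 extracellular matrix genes tested, 7 fell in the pigmented line, 1 rose and 26 did not pass, and 13 fell and 3 rose when adjusted over the list alone. With the integrity pair as a block 12 fell and 2 rose. Beside Mgp, the collagen genes Col11a1 (-5.30), Col6a1 (-4.97), Col4a1 (-4.11) and Col6a3 (-4.08) fell, the proteoglycan gene Bgn fell by 3.13 and the fibronectin gene Fn1 fell by 2.48. Mmp2, a gelatinase, rose by 3.09 ± 0.43. Camera gave an adjusted p of 1.82e-05, against an adjusted p = 0.485 with an estimated correlation. Of 25 cell adhesion genes, the integrin genes Itgb5 (-2.61) and Itga3 (-2.21) fell, L1cam fell by 1.90 and Itga4 rose by 2.49. When adjusted over the list alone, 6 fell and 1 rose, as many as with the integrity pair as a block. The camera adjusted p was 0.00540, against an adjusted p = 0.376 with an estimated correlation. With the date as a block none of these 4 genes passed, at adjusted p-values from 0.0607 (Itgb5) to 0.178 (L1cam).

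**Figure D2:**
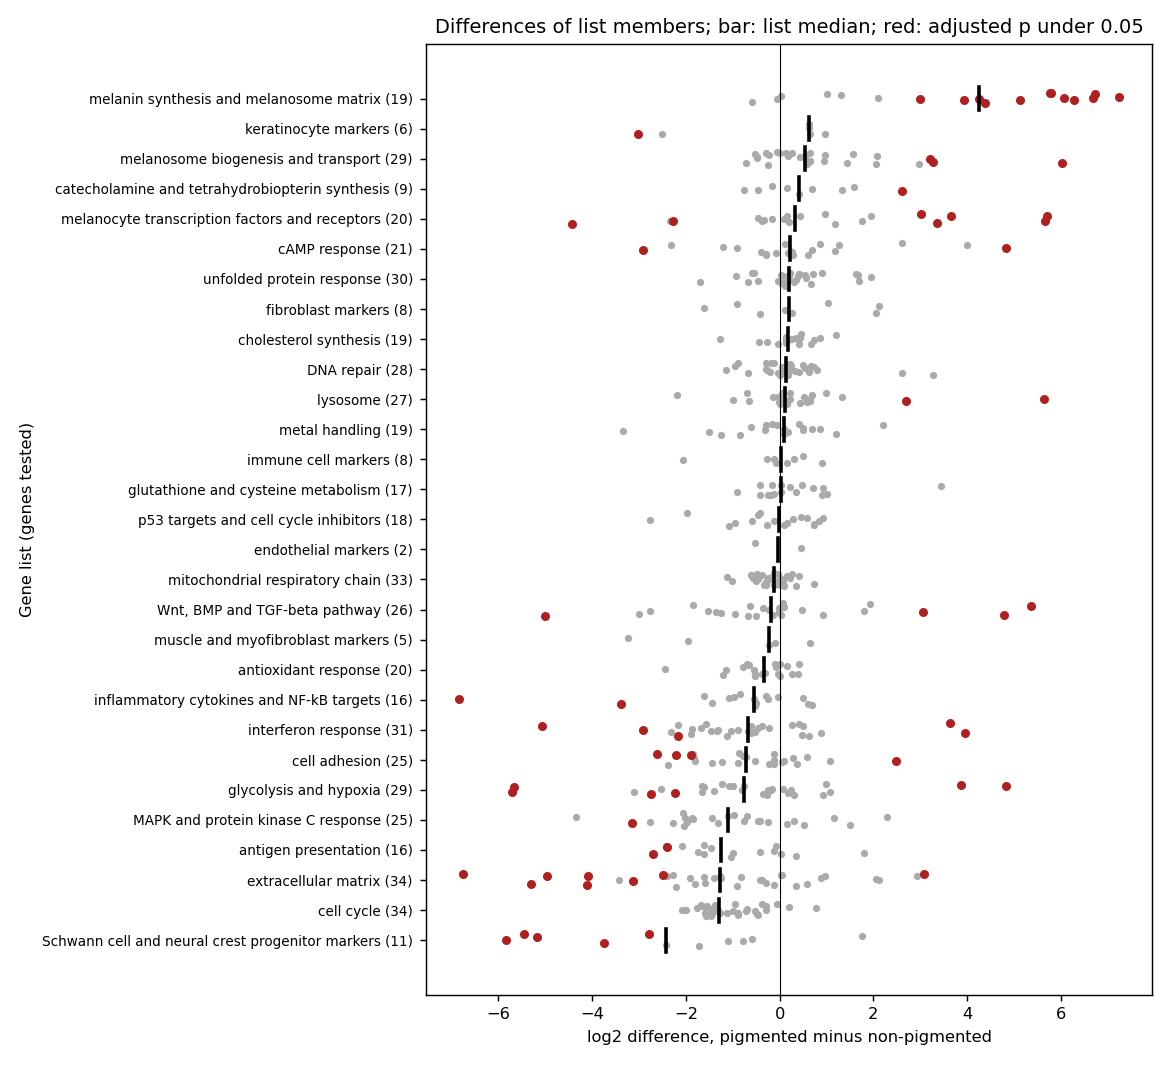
Log2 difference, pigmented minus non-pigmented, of each tested member of the 29 lists, with black bars at list medians and red points for genes with an adjusted p under 0.05. The melanin list has a median of 4.25 and the Schwann cell and neural crest progenitor list one of -2.42.

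Of 16 antigen presentation genes, Tap1, a peptide transporter, fell by 2.69 ± 0.44 in 1 of 4 probe sets and Erap1, a peptidase, fell by 2.40 ± 0.42, while 8 fell when adjusted over the list alone and 7 with the integrity pair as a block. The list's camera adjusted p was 8.77e-05 and the adjusted p = 0.376 with an estimated correlation. With the date as a block neither gene passed (adjusted p of 0.0578 for Tap1 and 0.0805 for Erap1). Of 31 interferon response genes, Ifi27l2a fell by 5.08, Ifih1 fell by 2.92 and Gbp2 fell by 2.17, whereas Xaf1, in 1 of 2 probe sets, and Mx1 rose by 3.96 and 3.64. Ifih1 (adjusted p of 0.0600) and Gbp2 (0.134) did not pass with the date as a block. When adjusted over the list alone, 4 fell and 2 rose. The camera adjusted p was 0.00169, against an adjusted p = 0.652 with an estimated correlation, and it was 0.710 without pigmented replicate 1. The median was -1.28 within the intact pair of arrays and 0.02 within the pair with low 5′ signal. Of 16 inflammatory genes, Lcn2 and the protease gene Mmp3 fell, the latter by a log2 difference of -3.38, and the same 2 were counted when adjusted over the list alone. The camera adjusted p was 0.00540, against an adjusted p = 0.376 with an estimated correlation, and it was 0.118 without the filter on dim probe sets (list mean -0.44, against -1.04).

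Of 29 genes of glycolysis and hypoxia, 4 fell and 2 rose, and 8 fell and 2 rose when adjusted over the list alone. Under the integrity pair as a block 10 fell and 2 rose. Pfkp, a phosphofructokinase, fell by 5.70 ± 0.41 and Bnip3, a mitophagy receptor induced by hypoxia, fell by 5.67 ± 0.52, with Egln3 (-2.74) and P4ha2 (-2.23; adjusted p of 0.152 with the date as a block). The enolase gene Eno2 rose by 4.82 and the glucose transporter gene Slc2a3 by 3.86. Camera gave the list an adjusted p of 0.00215, against an adjusted p = 0.376 with an estimated correlation.

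Of 25 genes of the MAPK and protein kinase C response, Spry1, a feedback inhibitor, fell by 3.16 ± 0.49, and 6 fell and 2 rose when adjusted over the list alone. With the integrity pair as a block 6 fell and 1 rose. For this list camera gave an adjusted p of 0.00169, against an adjusted p = 0.627 with an estimated correlation, and 0.110 without pigmented replicate 2. In the Wnt, BMP and TGF-beta list of 26 genes, Dkk3, Nkd1 and Axin2 rose by 5.37, 4.79 and 3.06 and Wnt4 fell by 5.01. When adjusted over the list alone, 4 rose and 6 fell, with the integrity pair as a block 5 rose and 5 fell, and the camera adjusted p was 0.419. In the cAMP response list of 21 genes, Nr4a3 rose by 4.82 and Akap12 fell by 2.92. Of 27 lysosome genes, Atp6v0d2, a proton pump subunit, rose by 5.64 and Tfeb, a regulator of lysosomal genes, by 2.69. The list of catecholamine and tetrahydrobiopterin synthesis, with 9 genes tested, also holds genes of tyrosine breakdown. Fah, which is among the latter, rose by 2.60, and the other 8 did not pass. With the date as a block Akap12 (adjusted p of 0.0521), Tfeb (0.0771) and Fah (0.0849) did not pass. When adjusted over the list alone, 3 rose and 2 fell among the cAMP genes, 2 rose and 1 fell among the lysosome genes, and 1 rose in the catecholamine list. With the integrity pair as a block 3 rose and 2 fell among the cAMP genes. In that fit 3 rose in the lysosome list and 2 in the catecholamine list. These 3 lists had camera adjusted p-values of 0.432, 0.154 and 0.111, the last falling to 0.0392 without non-pigmented replicate 2.

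No gene was called by limma in the lists of glutathione metabolism, the antioxidant response, metal handling, the unfolded protein response, p53 targets, DNA repair, cholesterol synthesis or the mitochondrial respiratory chain. These lists held, in that order, 23, 22, 23, 30, 23, 28, 19 and 33 genes on the array. Of these, 17, 20, 19, 30, 18, 28, 19 and 33 were tested. In that order 3, 0, 3, 3, 2, 2, 0 and 1 of their genes had an unadjusted p under 0.05, and 1 gene, of the p53 list, passed when adjusted over the list alone. Their camera adjusted p-values were 0.419, 0.0933, 0.818, 0.282, 0.419, 0.432, 0.419 and 0.284. With the integrity pair as a block 5 genes of these lists passed, namely Sod3 (adjusted p of 0.0390), Cp (0.00584), Cdkn1a (0.00784), Phlda3 (0.0225) and Brca1 (0.0198). Without pigmented replicate 2 the mean of the cholesterol list went from 0.22 to 0.90 (camera adjusted p of 0.00164) and that of the unfolded protein list from 0.28 to 0.60 (0.00947). With unique probe sets the antioxidant list passed (0.0383). The filter left Cth (difference 3.58) and Slc7a11 (-2.42) of the glutathione list untested. The simulations missed most changes of a log2 size of 2, so the absence of calls does not exclude differences of that size.

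None of 34 cell cycle genes was called between the lines by limma, nor when adjusted over the list alone, with 1 at an unadjusted p under 0.05, and the differences of Mcm6 (-1.99), Cdca8 (-1.58), Mcm5 (-1.59) and Tpx2 (-1.77) did not pass. The list mean was -1.07 with a camera adjusted p of 0.00430, against an adjusted p = 0.687 with an estimated correlation. The median difference between the lines was -3.80 within the first date and 1.37 within the second, but each date pairs an intact with a low 5′ array. It was -0.16 within the intact pair and -2.26 within the low 5′ pair. With the integrity pair as a block the camera adjusted p was 1.10e-05. Without pigmented replicate 2 the list mean was 0.61 (camera adjusted p of 0.0153), and without non-pigmented replicate 1 it was -0.29 (camera adjusted p of 0.461). Between the low 5′ and the intact array of a line, the median was -1.46 in the non-pigmented line, with 32 of 34 genes lower, and -3.53 in the pigmented line, with 34 of 34 lower. By limma 0 of the 34 were called in this comparison, with 31 at an unadjusted p under 0.05, the camera adjusted p was 3.35e-19, against an adjusted p = 0.907 with an estimated correlation, and the fry adjusted p was 0.465.

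**Figure D3:**
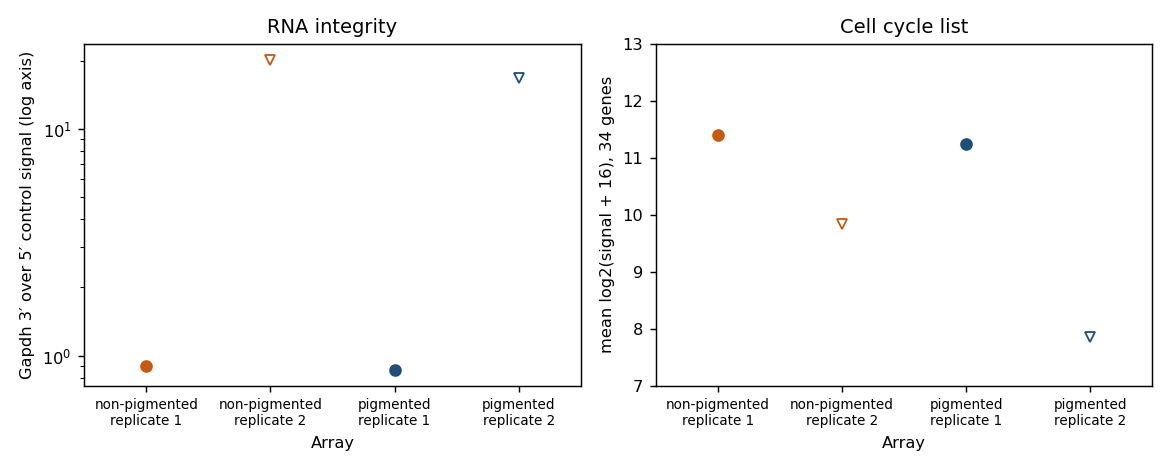
Gapdh 3′ to 5′ control signal ratio on a log axis (left) and mean log2(signal + 16) of 34 cell cycle genes (right) in each array, with open triangles for the arrays with low 5′ signal. The arrays with ratios of 20.2 and 16.8 have the lower cell cycle means, 9.84 and 7.86, against 11.40 and 11.24.

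Between the dates 0 genes were called by limma with the group as a block, and 78 had an unadjusted p under 0.05. In this fit the dates are judged against the RNA integrity split. Its log2 differences spread more than those of the dates (SD 0.787 against 0.455), so 0 calls do not show that the date had no effect. The smallest p-values belonged to Kcne4 (2.12), Tmprss5 (2.06) and Sucnr1 (2.04) among positive and Zap70 (-1.98), Aplp1 (-1.83) and Cmah (-1.74) among negative differences. Across genes the line difference within the first date correlated with that within the second at 0.339, and 50.8% of all genes had the same sign in both. Between the low 5′ and the intact arrays 0 genes were called by limma and 2789 had an unadjusted p under 0.05, with a smallest adjusted p of 0.0891. By camera the cell cycle (adjusted p of 3.35e-19), MAPK (0.000463), cholesterol synthesis (0.00110) and extracellular matrix (0.0372) lists were lower in the low 5′ arrays and the interferon list (0.000463) was higher, each at an adjusted p = 0.907 with an estimated correlation. That last test had 1 residual degree of freedom and passed no list.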

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

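The tests in this part were chosen only after the results were seen, and those for other cells, slower growth and the date were changed again after their outcome was known. The control probe sets, which enter no comparison, set a pair of arrays apart. The Gapdh 3′ to 5′ ratio was 20.2 in non-pigmented replicate 2 and 16.8 in pigmented replicate 2, and the 18S control signal was 5329 and 973, against 25.6 and 70.8 in the other arrays. Of 4054 tested probe sets without a gene name, 27 were called by limma in a fit over all probe sets, 10 higher and 17 lower in the pigmented line.

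Of the 19 melanin list genes tested, 12 were lower in the non-pigmented line and the other 7 did not pass. Replacement of most melanocytes by other cells stays open: 11 of the 19 tested members had a smaller difference than Oca2 by over 2 combined standard errors and the 7 others beside Oca2 did not. In the non-pigmented line 5 genes of the Schwann cell and neural crest progenitor list were higher, which do not all mark Schwann cells. A loss of 5′ signal does not account for the difference, since the list median was 4.13 within the intact pair. An exchange of 1 array of each line is argued against by the highest correlation between lines, 0.819, lying below the lowest within a line, 0.862, but a complete exchange of the lines would leave both values as they are and stays open. Also open is whether the difference came with the tyrosinase correction or with the separate history of the lines, which cannot be told apart because the labels describe 1 line per group.

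The cell cycle list had medians of -1.46 and -3.53 between the low 5′ and the intact array of a line, but 0 genes were called by limma (31 at an unadjusted p under 0.05), and the camera call did not hold at an adjusted p = 0.907 with an estimated correlation, nor by fry (0.465). A loss of signal that affects genes of the same level alike is argued against: 0 of 10000 random lists matched on level had a median as low as that of the cell cycle list, in either line (lowest random medians -0.58 and -0.73). The list was picked after its fall was seen, and random lists lack its correlation between genes (estimated at 0.77), so the count is no p-value. The matching did not include the position of probe sets along the transcript, so a loss specific to distant probe sets stays open. Slower growth of these cultures may also be involved, but p53 targets and cell cycle inhibitors had medians of 0.057 in the pigmented and 0.165 in the non-pigmented line and a camera adjusted p of 0.426, which does not decide it.

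Arrays of the same date deviated from their line's mean in opposite directions. The correlation of -0.51 between their deviations does not exclude a batch effect of the date, since with 2 arrays per line it is by construction the value of the integrity pairs, 0.51, with its sign turned. If the dates of one line are exchanged, it becomes 0.51 for the same reason. A smaller effect of the date, dates exchanged in the titles and RNA handling unrelated to the dates cannot be told apart with 2 arrays per line.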

How the results depend on the processing

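The alternatives with the RNA integrity pair were chosen only after the data were seen. Against 422 called genes, the date as a replicate block gave 392, of which 345 were shared, and 10 settings of normalization, filter, variance model, probe set choice and pseudocount gave 301 to 443. The integrity pair as a replicate block gave 884 (341 higher, 543 lower). The integrity pair is the date pairing crossed, with 884 calls against 392. Leaving out each array gave 234 to 772 calls (100 to 267 higher, 127 to 505 lower), with fewer samples in each. The correlation across genes between the dates' differences was 0.339, 0.275 without the filter and 0.721 between the integrity pairs; the causes were not tested. The Tyr difference passed under every setting run, at 5.95 to 7.42. Of 93 genes taken by the naming rule for the comparison of the lines, 66 were called and 0 of these reversed. Their selection largely fixes this, since all called genes had the same direction in both dates and in both integrity pairs. Across settings, results for named genes were the same in 1317 cases, lost the call in 96, gained it in 35 and reversed in 2; for lists the numbers were 449, 8, 6 and 1. All 3 reversals came without pigmented replicate 2, for the cell cycle list (0.61; range without single arrays -2.76 to 0.61), Mcm5 (0.21; -3.39 to 0.21) and Tpx2 (0.091; -3.64 to 0.091); the cause was not tested. Among the 93 genes of the naming rule, the date block ended the call of 10 and gained it for 2, and it ended the call of no list. Other called genes given above also missed under it. The integrity block gained 11 of the 93 genes and ended the call of none. It ended the call of the melanocyte transcription factor list (camera adjusted p of 0.0679). By camera that list also missed at 0.139 without the filter and 0.233 with unique probe sets, and its mean was 0.85 without pigmented replicate 1. The inflammatory list missed at 0.118 without the filter. The catecholamine list passed at 0.0310 with the filter at the 60th percentile and 0.0329 with the mean of probe sets. Signal over background could not be measured here, so the limit for dim genes is unknown.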

Other observations

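The tests of the cartilage, germline and glia lists were fixed before their results were seen, but after the leading genes of the comparison were known. The allowances for the spread over list members and for dim genes were added after the results of the germline and glia tests were seen. Of 25 genes typical of cartilage on the array, 12 were bright enough to test, and 2 of these fell in the pigmented line. Cnmd, an angiogenesis inhibitor of cartilage, fell by 5.81 ± 0.57 and Col9a1, a cartilage collagen gene, fell by 4.37 ± 0.65, and the same count of 2 fell when adjusted over the list alone. Ccn2 had a difference of -3.43 with an adjusted p of 0.223 (0.0348 with the integrity pair as a block), and the regulator Sox9 and the proteoglycan gene Acan had differences of -0.16 and -0.42.

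A hypothesis from Col2a1, Mgp and Col11a1 was that the non-pigmented line expresses a cartilage programme. The mean of the 12 tested genes was -1.75 and the median -1.21, with a camera adjusted p of 0.000405, as the hypothesis predicted. With an estimated correlation the camera adjusted p was 0.436, the fry adjusted p was 0.137, and Sox9 hardly differed. The filter on the mean of the 4 arrays can keep a gene high in 1 line only and drops genes dim in both. The list mean may therefore overstate the shift. A general release of germline genes was proposed for Rhox5. The rule set in advance counted a list mean near 0 or a camera p over 0.05 against it. The list mean was 0.59, opposite to Rhox5, with an unadjusted camera p of 0.160, so by that rule the release was not met. However, only 4 of the 24 germline genes on the array were bright enough to test. In the non-pigmented line 3 of these lay within a log2 value of 1 of the filter or below it. With the allowance for dim genes, added later, the release was left undecided, since so few dim genes cannot exclude it. A broader glial programme, proposed for S100b, Gfap and Nes, was also not met by the rule set in advance. The mean of 16 genes was 0.16 ± 0.51 (SE over members), with a camera adjusted p of 0.941. Members went both ways, with Osmr, a cytokine receptor gene, rising by 6.24 ± 0.67. With the allowance for the spread over members, added later, the glial programme was left undecided.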
